A study of Mus musculus with 16 samples.

How the data were processed

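ATAC-seq marks open chromatin with the Tn5 transposase, which inserts adapters where DNA is accessible. The series applied it to spermatogenic cells purified from wild-type and Scml2-knockout (Scml2-KO) mice at 4 stages. Thy1+ spermatogonia (Thy1), a fraction that holds stem and progenitor cells, and c-Kit+ spermatogonia (cKit), the differentiating fraction, came from testes at postnatal day 7. Pachytene spermatocytes (PS) and round spermatids (RS) came from adult testes. Each of the 8 groups had 2 libraries, so 16 libraries entered. Per the labels, about 500000 spermatogonia, 250000 PS or 1000000 RS went into each reaction, fragments of 250 to 500 bp were taken from a gel, and 75-bp single reads were sequenced. Stage and age cannot be separated between the P7 and the adult cells. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

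The deposited files were peak lists, called for each library on its own rather than on pooled replicates. Bowtie 1.1.1, MACS2 2.1.0.20140616 and the mouse build mm10 are named in the submitters' processing notes, whereas the options and threshold of the peak caller are not given in the sources used here. Every line of a list was a summit, and a peak with several summits took several lines, and lines with the same peak were joined. Of 1431525 lines, 576 on the mitochondrial chromosome were left out of all comparisons, and the others gave 1111092 peaks on 21 chromosomes. The pileup column was a signal value, the coverage at the summit as the authors deposited it, not scaled to library size. The fold enrichment was a ratio deposited by the authors. Its values equalled the pileup plus 1 over a background plus 1, and this background was the same for all lines of a list, within 1.99e-05. Significance was deposited as −log10 p and −log10 q, per the file headers, and the lowest −log10 q of a list lay between 1.30 and 2.09. Peak length in bp, per the file headers, equalled the end minus the start plus 1, so coordinates count from 1. The authors' gene and region names for each peak were also deposited, with no rule stated in the sources used here. Scores and folds are the authors' values and were used here only to describe, rank or filter peaks within a list.

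The number of reads per library is unknown here, and the lists held 17813 to 164060 peaks. Whether list length followed depth or signal quality was not tested, and the background of the pileup, 0.937 ± 0.307 in replicate 1 and 0.968 ± 0.404 in replicate 2 (SD, n = 8 each), did not follow it. Whether a library has a peak is the measurement. A missing peak means that none passed the caller's threshold in that library, not that chromatin was closed. Wilson 95% confidence intervals are given for shares of single libraries, and they cover counting error only. No 2 libraries had identical lists.

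Transcription start sites (TSS) came from the transcripts in the authors' annotation, 23576 positions of 21311 genes, of which 987 genes were named only together with another gene and were matched by position to the RefSeq table of GRCm38.p6. A gene counted as open in a library where a peak overlapped 1 kb on either side of a TSS by at least 1 bp, and this is called a promoter peak. Peaks of all libraries that overlapped by at least 1 bp were merged into 367750 regions with a median length of 228 bp, and a region counted as open in a library with a peak in it. Genes that share a promoter, such as Tmsb15b1 and Tmsb15l, cannot be told apart.

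P7 spermatogonia (8 libraries of Thy1 and cKit) were compared with adult germ cells (8 libraries of PS and RS) by a two-sided Fisher exact test per gene or region on the number of libraries with a peak, for features open in 5 to 11 of the 16 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each step between consecutive stages compared 4 with 4 libraries, where the smallest exact p is 0.0286. For these steps, features open in all 4 libraries of a stage and in 0 of 4 of the other were counted, beside the same count in the other splits of the 8 libraries. A Fisher exact test of the steps, adjusted over the features open in 4 of 8 libraries, was added after the data were seen. Chance alone puts 2.86% of features open in 4 of 8 libraries into such a pattern. Genotype was tested over all stages with an exact conditional test that permutes the labels within each stage (1296 arrangements, two-sided), over features able to reach p = 0.05. Within a stage, 2 against 2 libraries allow no two-sided p under 0.333, so features in both libraries of a genotype and neither of the other were counted, with no test. Shares of peaks near a TSS, on X and on Y, and the share of each gene list with a promoter peak, were compared by two-sided exact permutation tests (12870 arrangements for spermatogonia against adult cells, 70 for PS against RS, 1296 for genotype). Whether the genotype effect differed between stages was not among the tests fixed beforehand. It was tested by assigning 2 of the 8 log2 ratios of KO to wild type to a stage in all 28 ways. This allows no p under 0.0357 and no adjusted p over the 4 stages under 0.143, so no stage could pass.

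The groups, most tests, 14 gene lists, naming rule and most alternatives were fixed before the data were examined. The lists covered spermatogonial stem and progenitor cells, differentiating spermatogonia, meiotic prophase, the pachytene program, spermatids and sperm, Sertoli, Leydig, peritubular and smooth muscle, immune and endothelial cells, Polycomb and SCML2 partner genes, Hox and developmental regulators, sex chromosome silencing and DNA damage response, and a housekeeping reference. Of their 338 genes, 335 had a TSS in the files under the listed or an older symbol. Named genes were Scml2, then from each list up to 4 genes with the largest difference in libraries (at least 5 of 8, or 4 of 4), and 10 genes in each direction over all genes (5 within a stage). Ties were ordered by the median fold enrichment of the promoter peak, and symbols starting with Gm and a digit, Mir, LOC, Snor, Olfr or Vmn, or ending in Rik, were left out of the second part. The text does not describe 2 genes that this rule gives. Up to 3 regions in each direction followed the same order.

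Alternatives were a −log10 q of at least 5, a fold enrichment of at least 5, the same number of peaks in every library (the 17813 with the highest −log10 q), a TSS window of 500 bp, the authors' own annotation, regions built from summits with 250 bp on either side, all features tested, shares of covered bases, list shares minus the share of all genes, each genotype alone, labels permuted within replicate numbers, and leaving out each library. Libraries of the 2 genotypes of a stage with the same replicate number deviated together from their group means in 4 of 4 stages (correlation 0.226 to 0.424), as did those of Thy1 and cKit (0.105 to 0.237) and of PS and RS (0.128 to 0.296). The numbers were therefore taken to pair the libraries in these comparisons. This rests on the data, since the labels name no shared animal, litter or day, and with the same number of peaks in every library the lowest correlations were 0.0965, 0.0224 and 0.123. Across cKit and PS (0.0919 to 0.152) and spermatogonia and adult cells (−0.00273 to 0.181) the numbers were not taken to pair libraries. The main tests of spermatogonia against adult cells took all 16 libraries as independent, so their p-values may be too small. BioWardrobe record numbers, also in the labels, run on between genotypes in both PS replicates but lie apart in both Thy1 replicates. In replicate 2 those of PS and RS lie apart from those of spermatogonia. Whether they mark batches is not stated. No genome of the build was used here, so 14 planned motif tests were not run.

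The tests were tested on simulated data drawn with the libraries' own rates for the 21311 genes, of which 200 were changed. Each library was drawn independently, with no link between libraries of the same replicate number. With presence of 95% against 5%, the comparison of spermatogonia with adult cells recovered 85.0% of changed genes and called 3 others. The genotype test recovered 45.0% and called 1 other. With 80% against 20%, both recovered 0% after adjustment, and the genotype test 47.5% at an unadjusted p under 0.05. Complete separation with 95% against 5% recovered 68.5% for Thy1 against cKit, 66.0% for cKit against PS and 65.0% for PS against RS, and it also picked 19, 22 and 31 unchanged genes. In the data, splits that ignored stage gave up to 130, 196 and 215 genes in these steps. The simulated counts of unchanged genes called may therefore be too low. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.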

Results

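Open chromatin was profiled in 16 libraries from Thy1+ spermatogonia (Thy1), c-Kit+ spermatogonia (cKit), pachytene spermatocytes (PS) and round spermatids (RS) of wild-type and Scml2-KO mice, with 2 libraries per group. SCML2 is a germline Polycomb-related protein known to act on the sex chromosomes and on the germline gene program. The lists held 135892 and 75038 peaks in Thy1 wild type, 110680 and 52113 in Thy1 Scml2-KO, 83378 and 32356 in cKit wild type, and 91480 and 17813 in cKit Scml2-KO. In the adult cells they held 85348 and 24751 in PS wild type, 105751 and 21878 in PS Scml2-KO, 52379 and 31070 in RS wild type, and 164060 and 27105 in RS Scml2-KO. Replicate 1 had the longer list in each of the 8 groups. Agreement of 2 libraries was taken as the Jaccard index, the merged regions open in both over those open in either. Its median was 0.310 between replicates of a group and 0.348 between genotypes of a stage. Between stages of a class it was 0.316, and between spermatogonia and adult cells 0.156. With the same number of peaks in every library, these medians were 0.598, 0.594, 0.512 and 0.328.

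The Scml2 promoter (chromosome X, TSS at 161162772) had a peak with a fold enrichment of 10.3 and 11.5 in Thy1 wild type, 11.7 and 7.15 in Thy1 Scml2-KO, and 8.90 and 3.599 in cKit wild type. In cKit Scml2-KO it was 6.93 in replicate 1, with no peak in replicate 2. PS wild type replicate 1 had a peak at 6.19 and RS wild type replicate 1 at 4.98, whereas replicate 2 of both groups and all 4 adult Scml2-KO libraries had none. Because a promoter can stay accessible when the gene is deleted elsewhere, these values do not check the knockout labels.

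Between spermatogonia at P7 and adult germ cells, a part of the meiotic and spermatid genes gained promoter peaks. Spo11, which makes the breaks that start meiotic recombination (chromosome 2, TSS at 172979842), Tex12 and Hormad1, structural proteins of meiotic chromosomes, Piwil1, a PIWI protein of pachytene piRNAs, and the sperm genes Prm3, Acr, Tnp1 and Actl7a had a promoter peak in 8 of 8 adult and 0 of 8 spermatogonial libraries. The reverse held for Zfand6 (chromosome 7, TSS at 84679351), St8sia4, a polysialyltransferase, Glrx, a glutaredoxin, Calcrl, Trim21, Enpp2, Clec2d, Abi3bp and the X-linked Sh3bgrl and Igbp1. Each of these genes had an adjusted p of 0.00358 by Fisher's exact test, which took the 16 libraries as independent. Among 3919 genes tested, 967 were higher in spermatogonia, 113 of them with complete separation, and 333 were higher in adult cells, 57 with complete separation. Of the 967 genes, 119 were on X, against 0 of the 333, while X held 4.09% of all genes.

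Spermatid and sperm genes rose from 25.9% ± 8.65 (SD, n = 8) of the list with a promoter peak in spermatogonia to 75.6% ± 18.7 (n = 8) in adult cells, with an adjusted p of 0.00109 by the exact permutation test over 14 lists. Of its 40 genes, 16 were called higher in adult cells over all genes and 19 adjusted over the list alone. Meiotic prophase genes rose from 61.2% ± 19.2 to 94.6% ± 5.05 (SD, n = 8 each, exact adjusted p = 0.00109), with 4 of 28 called and 7 adjusted over the list alone. The fourth called gene of this list was Majin, a telomere attachment protein listed as 1700123I01Rik, in 6 of 8 adult and 0 spermatogonial libraries (adjusted p = 0.0247, Fisher's exact test). Pachytene program genes stood at 74.0% ± 16.7 and 88.0% ± 10.96 (SD, n = 8 each) and did not pass (exact adjusted p = 0.108). They did pass, higher in adult cells, with lists of equal length (39.4 points, exact adjusted p = 0.000435), a −log10 q of 5 or more (25 points, 0.0231), a fold enrichment of 5 or more (23.1 points, 0.0246), minus the share of all genes (−19.95 points in spermatogonia, 0.00218) or without RS Scml2-KO replicate 2 (0.0469). In that list Piwil1 and Tdrd1, another piRNA factor (8 adult and 2 spermatogonial libraries), were higher in adult cells, and the glucose transporter Slc2a3 was higher in spermatogonia (8 and 1), 3 calls over all genes and 3 adjusted over the list alone. Stem and progenitor genes stood at 65.9% ± 18.98 and 51.1% ± 10.8 (exact adjusted p = 0.115, SD, n = 8 each, or 0.0389 and 0.0346 without replicate 2 of cKit wild type or Scml2-KO). With lists of equal length their difference turned to −2.27 points (exact adjusted p = 0.618). In this list the syndecan Sdc4 was the single gene called by either adjustment, in 7 spermatogonial and 0 adult libraries. Differentiating spermatogonia genes stood at 71.4% ± 18.7 and 62.5% ± 13.8 (exact adjusted p = 0.380, SD, n = 8 each). Here Dmrtb1, a regulator of the exit from mitosis, was the single call by either adjustment and was higher in adult cells (8 against 2), although with lists of equal length the list itself passed 13.7 points higher in spermatogonia (exact adjusted p = 0.0133), while Upp1 had peaks in 8 spermatogonial and 3 adult libraries and was not called.

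Promoters of somatic marker genes also carried peaks in more spermatogonial than adult libraries. Sertoli cell markers fell from 77.4% ± 13.6 to 33.9% ± 13.3 (SD, n = 8 each, exact adjusted p = 0.00145), with 6 of 21 called over all genes and 7 adjusted over the list alone. They included Rhox8 and Cst12 (7 against 0) and Clu (8 against 2). Peritubular and smooth muscle markers fell from 83.3% ± 17.8 to 34.4% ± 21.6 (SD, n = 8 each, exact adjusted p = 0.00381), with 2 of 12 called (Acta2, 8 against 2, and Lmod1, 6 against 0) and 6 adjusted over the list alone. Col1a2 (8 against 3) and Pdgfrb (7 against 2) were not called over all genes. Endothelial markers fell from 55.2% ± 18.3 to 22.9% ± 14.6 (SD, n = 8 each, exact adjusted p = 0.0113), with 3 of 12 called by either adjustment over all genes or over the list alone, namely Cdh5 (8 against 1), Kdr (8 against 2) and Tek (6 against 0). Immune markers fell from 21.6% ± 13.7 to 3.41% ± 4.70 (SD, n = 8 each, exact adjusted p = 0.0152), with 0 of 11 called by Fisher's exact test over all genes and 0 adjusted over the list alone, and Cd14 (7 against 2) had the largest difference. Leydig and steroidogenic markers stood at 47.9% ± 17.7 and 32.3% ± 8.26 (SD, n = 8 each, exact adjusted p = 0.102), with 1 of 12, Nr5a1 (6 against 0), called both over all genes and adjusted over the list alone. The Leydig list passed without cKit Scml2-KO replicate 2 or PS Scml2-KO replicate 1 (exact adjusted p = 0.0163 and 0.0452), and with a −log10 q or a fold enrichment of 5 or more (19.8 points each, exact adjusted p = 0.0299 and 0.0272). With lists of equal length, the endothelial, immune and Leydig lists did not pass (exact adjusted p = 0.166, 0.233 and 1), and the Leydig difference was 0 points.

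Hox and developmental regulators, typical Polycomb targets, fell from 62.8% ± 18.1 to 40.8% ± 14.1 (SD, n = 8 each, exact adjusted p = 0.0420). The transcription factor genes Pax9 and Tbx3 (8 against 1), Olig1 (7 against 0) and Tbx2 (8 against 2) were the 4 called of 50, and the count was 4 adjusted over the list alone. Polycomb and SCML2 partner genes (89.9% ± 6.99 and 91.1% ± 2.86), sex chromosome silencing and DNA damage response genes (98.0% ± 4.28 and 96.0% ± 3.02) and housekeeping genes (100% ± 0 and 97.4% ± 3.10) did not pass (SD, n = 8 each, exact adjusted p = 0.843, 0.472 and 0.108). Only 1, 1 and 0 members of these lists had peaks in 5 to 11 libraries and could be tested. Of these, 0 were called over all genes, and 1, 1 and 0 adjusted over the list alone by Fisher's exact test. The 1 gene was Scml2 in both lists, with peaks in 7 spermatogonial and 2 adult libraries. With the same number of peaks in every library, DNA damage response genes stood 7 points lower in spermatogonia (exact adjusted p = 0.0355), Polycomb and SCML2 partner genes 12.9 points lower (0.0131) and housekeeping genes 8.85 points higher (0.0131). Minus the share of all genes, the difference for Polycomb and SCML2 partner genes was −7.22 points and passed (exact adjusted p = 0.00272), while the other 2 lists turned to −4.01 and −3.41 points and did not pass (0.128 and 0.355). The Hox and developmental list did not pass when any of 10 libraries was left out, namely both of Thy1, PS or RS wild type, replicate 1 of Thy1 Scml2-KO, cKit wild type or cKit Scml2-KO, or PS Scml2-KO replicate 2 (exact adjusted p from 0.0622 to 0.0746), or with the same number of peaks in every library (8.5 points, exact adjusted p = 0.0848) or a TSS window of 500 bp (21 points, exact adjusted p = 0.0544). DNA damage response genes passed without cKit Scml2-KO replicate 2 (exact adjusted p = 0.0411), and housekeeping genes without PS Scml2-KO replicate 1, RS Scml2-KO replicate 1 or its replicate 2 (exact adjusted p = 0.0449, 0.0449 and 0.0465) or with a −log10 q or a fold enrichment of 5 or more (8.85 and 7.81 points higher in spermatogonia, 0.0411 and 0.0359). In neither genotype alone did any of the 14 lists pass, where 4 libraries faced 4.

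**Figure D1:**
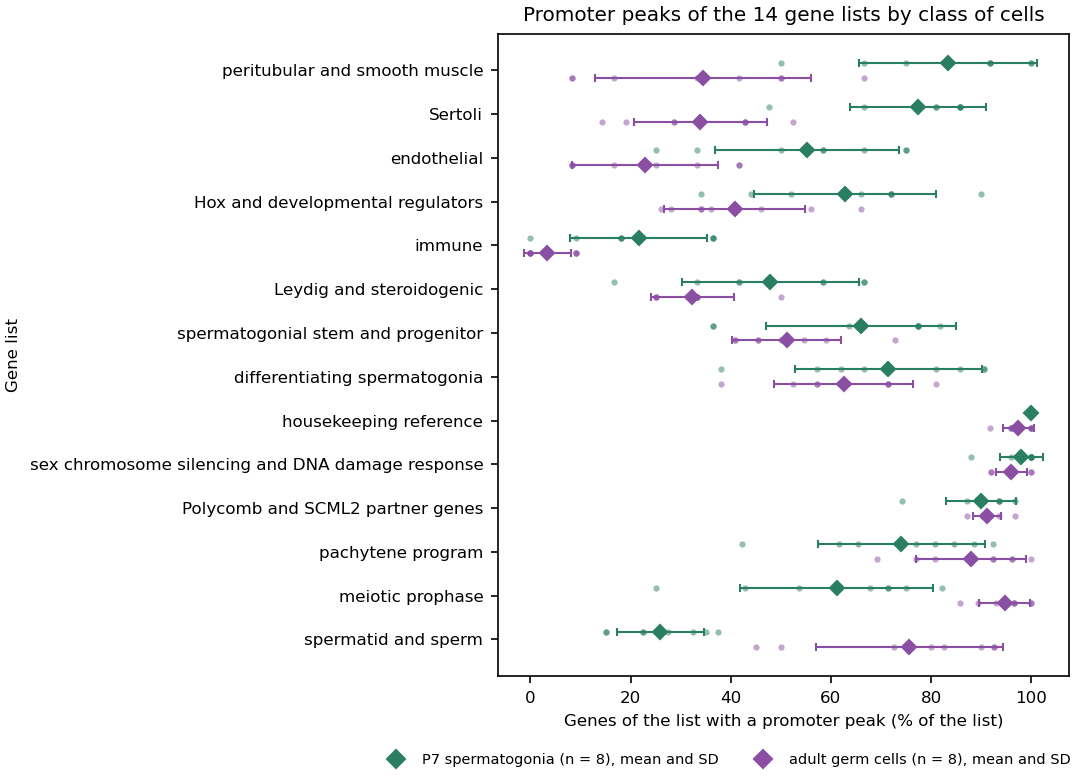
Share of each gene list with a promoter peak (x axis, % of the list) for 14 lists (y axis). Small points are libraries and diamonds with bars are the mean and SD of 8 libraries per class. Spermatid and sperm genes stand at 25.9% in spermatogonia and 75.6% in adult germ cells, and Sertoli markers at 77.4% and 33.9%.

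**Figure D2:**
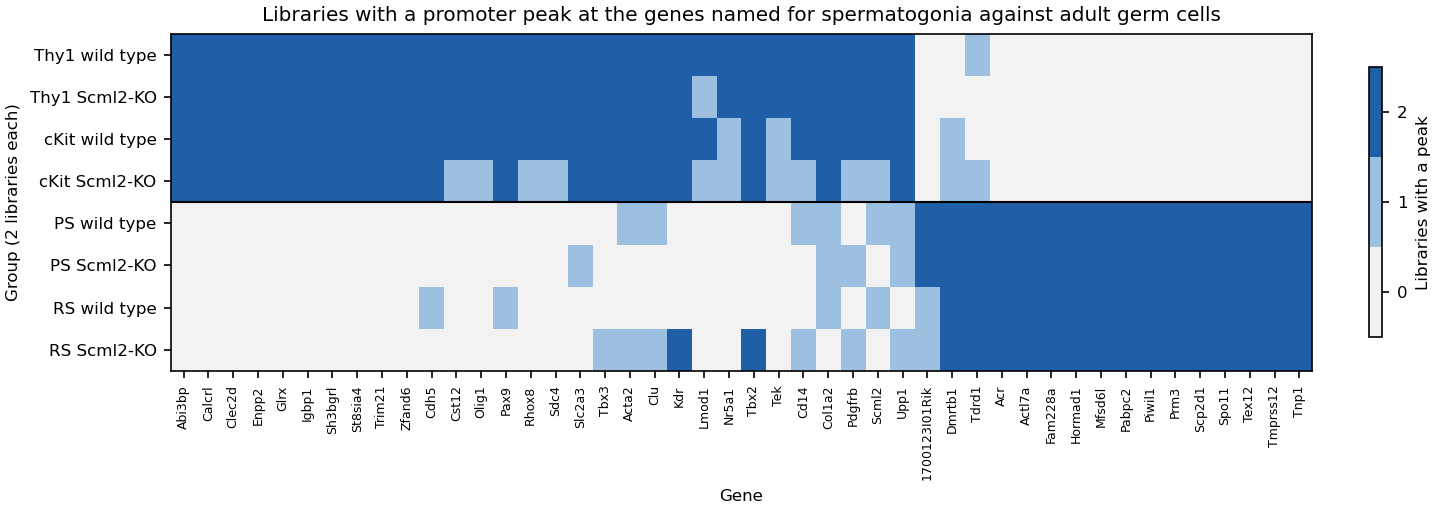
Number of libraries with a promoter peak (color, 0 to 2) at named genes (x axis) in each of the 8 groups (y axis). Genes are ordered from those in more spermatogonial libraries to those in more adult libraries, and the black line separates P7 spermatogonia from adult germ cells.

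Away from promoters the turnover was wider. Of 48340 regions tested, 22616 were called higher in spermatogonia and 7024 in adult cells, and 7.93% and 9.23% of these lay near a TSS. Complete separation held for 1260 and 608 of them, and adjustment over all features called far fewer regions and genes. X held 637 of the 22616 and 5 of the 7024, against 2.42% of all regions. An intergenic region near Mir181a-1 (chromosome 1, 137898148 to 137899192) was open in 8 spermatogonial and 0 adult libraries with a median fold enrichment of 25.7, as were the Zfand6 (24.0) and St8sia4 (23.5) promoter regions. In the reverse direction stood an intergenic region near Mir466b-3 (chromosome 12, 88522382 to 88523966, 32.6), an intron of Bmp5 (chromosome 9, 75890624 to 75892099, 30.2) and an intron of Zranb3 (chromosome 1, 128012648 to 128014038, 28.6). Without cKit Scml2-KO replicate 2, the shortest list, 2409 genes were called in place of 1300, and without PS or RS wild type replicate 1 the regions were 19220 and 19366 in place of 29640. Peaks with a −log10 q or a fold enrichment of 5 or more gave 15504 and 17313 regions. Lists of equal length gave 2129 genes (1314 higher in spermatogonia and 815 in adult cells) and 8010 regions (4422 and 3588). Scml2-KO alone gave 0 of both by Fisher's exact test, against 911 genes and 11748 regions in wild type alone. With 4 against 4 libraries all completely separated features share an exact p of 0.0286 and pass adjustment together or not at all. These counts therefore do not compare the genotypes.

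Within P7 testes, the Thy1 to cKit step asks how chromatin differs between the progenitor and the differentiating fraction. Promoters of 51 genes were open in all 4 Thy1 and 0 of 4 cKit libraries, and 0 genes showed the reverse. They included Vamp2, a vesicle fusion protein (chromosome 11, TSS at 69088528), Mst1, Phyhd1, Aar2, Tha1, Fam109b, Hap1 and the secreted or membrane signals Il33, Tnfsf18 and Vip. Regions followed, 1903 in all 4 Thy1 libraries against 9 in all 4 cKit libraries, with 5.04% of the 1903 near a TSS. The strongest Thy1 regions were intergenic near Tasp1 (chromosome 2, 139792265 to 139793126, median fold enrichment 16.8), in an intron of Rnf150 (chromosome 8, 82939770 to 82940614, 13.1) and intergenic near Rbpj (chromosome 5, 53371677 to 53372316, 12.4). The strongest cKit regions were intergenic near Msh6 (chromosome 17, 87896853 to 87897457, 7.59), upstream of Ccdc167 (chromosome 17, 29731632 to 29731942, 7.34) and in an intron of Agpat3 (chromosome 10, 78315032 to 78315479, 5.72).

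None of the 14 lists had a member among the 51 genes. Stem and progenitor genes stood at 75.0% ± 7.87 in Thy1 and 56.8% ± 23.6 in cKit (SD, n = 4 each), differentiating spermatogonia genes at 73.8% ± 11.3 and 69.0% ± 25.9, and Sertoli markers at 83.3% ± 2.75 and 71.4% ± 18.2, differences that were not tested. The lists were longer in Thy1 (93431 ± 37175 peaks) than in cKit (56257 ± 36631, SD, n = 4 each). Splits of these 8 libraries that ignored stage gave up to 130 genes and 4964 regions, with replicate 1 against replicate 2 the highest. Wild type alone separated 440 genes and 15416 regions and Scml2-KO alone 190 and 5578, while lists of equal length gave 47 genes in Thy1 against 11 in cKit and 258 against 148 regions, 406 in all. By Fisher's exact test with adjustment 0 genes and 0 regions were called (lowest adjusted p = 0.264 and 0.218). The count was 148 genes without Thy1 Scml2-KO replicate 2, 82 without Thy1 wild type replicate 2, 115 without cKit wild type replicate 1 and 137 without cKit Scml2-KO replicate 1, with 7566, 3335, 2844 and 3446 regions.

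Entry into meiosis was compared as cKit against PS. Promoters of 224 genes were open in all 4 PS and 0 of 4 cKit libraries, among them 4 meiotic prophase genes (Spo11, Tex12, Hormad1 and Majin, listed as 1700123I01Rik), Piwil1 of the pachytene program, and 5 spermatid and sperm genes (Tnp1, Tnp2, Prm3, Acr and Actl7a). Outside the lists stood Mroh2b (chromosome 15, TSS at 4898737, median fold enrichment 21.8), Topaz1, a germ cell factor (17.9), Tmprss12 (16.8), Scp2d1 (16.5), the centrin Cetn1 (15.5), Ppp1r27 (15.1) and Ttll8 (15.0). In the other direction, 279 genes were open in all 4 cKit and 0 of 4 PS libraries, including Zfand6, St8sia4, Glrx, Ticam1, Calcrl, Trim21, Gramd1a and the X-linked Sh3bgrl and Igbp1. The somatic markers Wt1, Col1a1, Pdgfra, Kdr and Cdh5 and the developmental regulators Pax9, Tbx2, Tbx3 and Gata6 were also among the 279.

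Spermatid and sperm genes thus had promoter peaks already in PS, at 66.9% ± 22.7 of the list, against 24.4% ± 10.9 in cKit (SD, n = 4 each), and meiotic prophase genes stood at 96.4% ± 2.92 against 55.4% ± 26.2. Regions numbered 2380 in all 4 PS and 2187 in all 4 cKit libraries, of which 10.5% and 14.8% lay near a TSS. The leading ones were those near Mir466b-3, Bmp5 and Zranb3 in PS and those near Mir181a-1, Zfand6 and St8sia4 in cKit. No other split of the 8 libraries gave as many genes (highest 196) or regions (highest 2098). The count of genes was 884 and of regions 12676 without cKit Scml2-KO replicate 2, and 7520 regions without PS Scml2-KO replicate 2. Wild type alone separated 1615 genes and 18977 regions, Scml2-KO alone 923 and 7503, and a −log10 q of 5 or more gave 2522 regions. By Fisher's exact test with adjustment 0 genes and 0 regions were called (lowest adjusted p = 0.0657 and 0.0574). The order of the directions turned with lists of equal length, to 465 genes in cKit and 644 in PS, and without cKit Scml2-KO replicate 1, to 280 and 315. Regions turned to 12200 in cKit and 6777 in PS in wild type alone, to 10283 and 2393 without cKit Scml2-KO replicate 2, and to 2667 and 2392 without cKit wild type replicate 2. They also turned without replicate 1 of PS wild type (2463 and 2403) or of PS Scml2-KO (2507 and 2395).

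From PS to RS few promoters separated. Promoters of 42 genes were open in all 4 PS and 0 of 4 RS libraries, and 26 showed the reverse. Those in PS included Mroh2b (median fold enrichment 21.8), the zinc finger genes Zik1 (16.6), Zfp954 (13.8) and Zfp54 (10.8), Penk, which encodes proenkephalin (13.4), Ppp1r14c, the kinase gene Lyn (10.9), Hoxc5, Vwa1 and Cdc42ep5, besides Aurkc, a meiotic kinase, and Sox1 from the lists. Those in RS included Smox, a spermine oxidase (10.98), Tnrc18 (9.79), Ppp1r18, Plscr3, the repressor gene Hic1, Ubqlnl, Rab26, Tmem150c, and Wt1 with its neighbor AI314831. Except for Mroh2b and Ubqlnl, each of these genes also had a promoter peak in at least 3 spermatogonial libraries.

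The regions numbered 348 in PS and 246 in RS. The PS set was led by the promoters of Mroh2b (chromosome 15, 4897645 to 4899222), 4930423M02Rik (chromosome 4, 5631714 to 5633061) and Crem, a regulator of spermatid genes (chromosome 18, 3299218 to 3300216, 16.9). The RS set was led by an intergenic region near Cdon (chromosome 9, 35359666 to 35360996, 13.8), the Smox promoter (chromosome 2, 131491380 to 131492855) and an exon of Hr (chromosome 14, 70567906 to 70568391, 9.99). Pachytene program genes stood at 96.2% ± 3.14 in PS and 79.8% ± 9.62 in RS, and spermatid and sperm genes at 66.9% ± 22.7 and 84.4% ± 9.87 (SD, n = 4 each), differences that were not tested. Splits that ignored stage gave up to 215 genes and 3754 regions. The counts were 122 genes and 997 regions without PS wild type replicate 1, 91 and 925 without its replicate 2, 96 and 757 without PS Scml2-KO replicate 1 and 137 and 1423 without its replicate 2, and for RS in the same order 107 and 913, 103 and 908, 199 and 1378, and 109 and 1126. Lists of equal length gave 324 and 1363, wild type alone 631 and 4740 and Scml2-KO alone 435 and 3976, while a −log10 q or a fold enrichment of 5 or more gave 105 and 143 genes. The order of the directions turned to 116 genes in PS and 319 in RS in Scml2-KO alone (972 and 3004 regions), against 480 and 151 in wild type alone (3331 and 1409 regions). It also turned without replicate 1 of PS wild type (45 and 77 genes), PS Scml2-KO (46 and 50) or RS wild type (51 and 56), and without replicate 2 of RS wild type (50 and 53) or RS Scml2-KO (51 and 58), and the regions turned with them. By Fisher's exact test with adjustment 0 genes and 0 regions were called (lowest adjusted p = 0.364 and 0.428).

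Loss of Scml2 left no promoter or region called over the 4 stages. The exact test within stages called 0 of 813 genes and 0 of 8560 regions. It needs the same direction in several stages. An effect confined to 1 stage, where 2 against 2 libraries allow no exact p under 0.333, could not be called by it. At an unadjusted p under 0.05 there were 6 genes higher in Scml2-KO and 8 higher in wild type, and 13 and 87 regions. These directions hung on single libraries, as the regions turned to 134 and 73 without cKit Scml2-KO replicate 2, 108 and 88 without PS Scml2-KO replicate 2 and 96 and 81 without RS Scml2-KO replicate 2, and stood at 4 and 226 without cKit Scml2-KO replicate 1. The genes turned without the same 3 libraries (23 and 4, 18 and 10, and 14 and 6) and without Thy1 wild type replicate 1, Thy1 Scml2-KO replicate 2 or cKit wild type replicate 1 (12 and 9, 17 and 8, and 17 and 10). Cyp26a1, which degrades retinoic acid (chromosome 19, TSS at 37697808), had a promoter peak in 7 of 8 Scml2-KO and 1 of 8 wild-type libraries (exact p = 0.0139, adjusted p = 1). Pgk2, the phosphoglycerate kinase of spermatogenic cells (chromosome 17, TSS at 40208609), had a promoter peak in 3 of 8 Scml2-KO and 8 of 8 wild-type libraries, as did Kcnv1 and Folh1 (exact p = 0.0278, adjusted p = 1). Caskin1, Cox7a1 and Lemd1 had peaks in 8 Scml2-KO and 3 wild-type libraries, Tmem151b in 7 and 2, and Usp50 in 1 and 6. The direction turned, to −1 library, for Cox7a1 and Lemd1 at a −log10 q of 5 or more. It also turned for Lemd1 with a TSS window of 500 bp and for Tmem151b with lists of equal length.

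Differences of 4 libraries stood at Gstm1, a glutathione transferase gene with a median fold enrichment of 23.4, Steap3, Hist1h1b, Actn1 and Plxdc2 (8 Scml2-KO and 4 wild type). In the other direction they stood at Nox4, Thsd7a and Kcnd2 (4 and 8), Syn1 and Edil3 (3 and 7) and Aldoart1 (1 and 5). The single region with complete separation lay between genes near Pcdh9 (chromosome 14, 90702645 to 90703339), in 0 Scml2-KO and 8 wild-type libraries (exact p = 0.00154, the smallest possible, adjusted p = 1). Among the 14 lists 0 passed the exact permutation test, 0 also at an unadjusted p under 0.05. The largest difference was 5.36 points and the lowest exact p 0.333 (adjusted p = 1).

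In Thy1, 15 promoters were open in both Scml2-KO and neither wild-type library, and 167 showed the reverse, counts with no test. Splits that put a wild-type with a Scml2-KO library gave up to 484 promoters and 24866 regions in Thy1, 1616 and 31401 in cKit, 1168 and 25362 in PS, and 871 and 12874 in RS. Scml2-KO promoters included Lnx1, Crybb3, Csf1r, a macrophage receptor gene, Cyp4f39 and Fam78a, and wild-type promoters Clec11a, Nyap1, Pgk2, Cntn5 and Svop, as well as Nanos2, a stem cell regulator, Sycp1, Dhh, Nkx2-1, Olig2 and Sox1 from the lists. Regions numbered 662 and 4890, led by a region upstream of Ptgr2 (chromosome 12, 84269593 to 84270805), an intron of Slc44a5 (chromosome 3, 154128988 to 154129557) and an exon of Zan (chromosome 5, 137454516 to 137455531) in Scml2-KO. Wild type was led by an exon of Jakmip3 (chromosome 7, 139020657 to 139021477) and intergenic regions near Zfy1 (chromosome Y, 259040 to 259493) and Mrap (chromosome 16, 90598619 to 90599547). At equal list length these counts were 440 and 533.

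In cKit, 24 promoters were open in Scml2-KO alone (AU015791, Slc2a10, Prss8, Oxct2b, Rapsn and, from the lists, Lin28a) and 26 in wild type alone (Cnnm1, Chst13, Timp2, Rundc3a, AU021063 and Pgk2). Of the regions, 106 were open in Scml2-KO alone, led by an exon of Asmt (chromosome X, 170674148 to 170675282), an intron of Fgf18 (chromosome 11, 33142741 to 33143259) and a region upstream of Gcgr (chromosome 11, 120515281 to 120516477). Another 458 were open in wild type alone, led by an intron of Galntl6 (chromosome 8, 57879345 to 57879777), a region upstream of 1700042G15Rik (chromosome 4, 57369891 to 57370343) and the Pgk2 promoter (chromosome 17, 40208080 to 40208953). At equal list length they were 292 and 586.

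In spermatocytes, the stage at which the sex chromosomes are silenced, most promoters open in wild type alone were X-linked. In PS, 184 promoters were open in both wild-type and neither Scml2-KO library, and 105 of these (57.1%) were on X. Of the 141 promoters with the reverse pattern, 0 were on X. The wild-type set included the X-linked BC065397, Trap1a, Tmsb15b1 and Tmsb15l, the autosomal Itgbl1, and from the lists Rhox13 and Sox3, X-linked genes of differentiating spermatogonia, and Smcp. In the Scml2-KO set stood Sec31b, Arhgap31, Lrfn2, Athl1 and Usp43, and from the lists Gata4, Hoxd9, Irx1 and Gusb. Regions numbered 1122 in wild type alone, 161 of them (14.3%) on X, and 553 in Scml2-KO alone, 0 on X. The former were led by a Pcdh9 promoter (chromosome 14, 93888793 to 93892035), a Pdk4 promoter (chromosome 6, 5495781 to 5497296) and an intron of Grm7 (chromosome 6, 111145653 to 111147363), and the latter by the promoters of Gstm1 (chromosome 3, 108017229 to 108018699) and Smpd1 (chromosome 7, 105553514 to 105555226) and an intron of Foxj2 (chromosome 6, 122825850 to 122826932). Of the 1168 promoters in the largest mixed split of PS, 22 were on X.

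In RS, 486 promoters were open in both Scml2-KO and neither wild-type library, and 85 in wild type alone. The Scml2-KO set included Angptl6, Pin1rt1, Arhgap24, the histone gene Hist2h3c2 and Rem2. From the lists it held the stem cell genes Eomes, Lhx1 and Utf1, Ccnd2, the Sertoli markers Gata4, Gdnf and Vim, Kdr, the Polycomb-related Pcgf2 and Sfmbt2, and Pax6, Six2, Tbx2 and Irx1. Wild type alone held Khdrbs2, Bai3, Epha3, Nox4 and Slitrk5, and no list gene. The regions numbered 2817 in Scml2-KO alone, led by the Gstm1 promoter region seen in PS, an intron of Insr (chromosome 8, 3220497 to 3221874) and the Gramd3 promoter (chromosome 18, 56431211 to 56432560). Wild type alone had 1201, led by the promoters of Khdrbs2 (chromosome 1, 32172079 to 32173388) and Robo2 (chromosome 16, 74410584 to 74412304) and an intergenic region near 1700023F02Rik (chromosome 10, 65908024 to 65908453). At equal list length the order turned, to 801 in Scml2-KO and 1464 in wild type.

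Chromosome X held a smaller share of the peaks in RS than in spermatogonia, a step that was not tested on its own. The 8 spermatogonial libraries had 2.19% to 2.62% of their peaks on X, and the 4 RS libraries 0.262% to 0.781%. PS wild type had 6.83% (95% CI 6.662 to 7.001) and 1.79% (1.63 to 1.96), whereas PS Scml2-KO had 0.483% (0.443 to 0.527) and 0.580% (0.488 to 0.690). With lists of equal length PS wild type had 2.85% and 1.60%, PS Scml2-KO 0.269% and 0.387%, and the spermatogonial libraries 2.20% to 2.67%. By the authors' annotation, 3330 of 5829 X peaks were intergenic in PS wild type replicate 1 and 75 of 443 in replicate 2. Promoter peaks followed at 581 and 290 X-linked genes in PS wild type and 198 and 90 in PS Scml2-KO. Means were 2.30% ± 0.143 in spermatogonia and 1.47% ± 2.21 in adult cells (SD, n = 8 each, exact permutation p = 0.368, adjusted p = 0.552 over 9 share tests). PS and RS stood at 2.42% ± 3.00 and 0.526% ± 0.237 (SD, n = 4 each, exact p = 0.2, adjusted p = 0.360). Over the stages the X share was 1.42% ± 0.998 in Scml2-KO and 2.36% ± 1.95 in wild type (SD, n = 8 each, exact p = 0.171, adjusted p = 0.360).

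The log2 ratio of Scml2-KO to wild type for the X share was −3.82 and −1.62 for replicates 1 and 2 of PS, and averaged −2.72 there and −0.11 in the other stages. The difference of −2.61 had an exact p of 0.0357 and an adjusted p of 0.143 over the 4 stages. Both are the smallest possible, so this test could not pass adjustment. In the ratio of group means, autosomes in PS ranged from −0.20 to 0.22 and X stood at −3.02. In RS the autosomes ranged from −0.57 to 0.40 on this measure and X stood at −0.36. Without PS wild type replicate 1 the spermatogonial X share stood 1.59 points above the adult share (exact p = 0.000155). The gap was also positive among peaks with a −log10 q of 5 or more (1.37 points, exact p = 0.00513), a fold enrichment of 5 or more (1.28, exact p = 0.00622) or lists of equal length (1.45, exact p = 0.00155). These p-values were not adjusted over the share tests. In Scml2-KO alone the gap was 1.84 points (exact p = 0.0286) and in wild type alone −0.19 (exact p = 1).

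**Figure D3:**
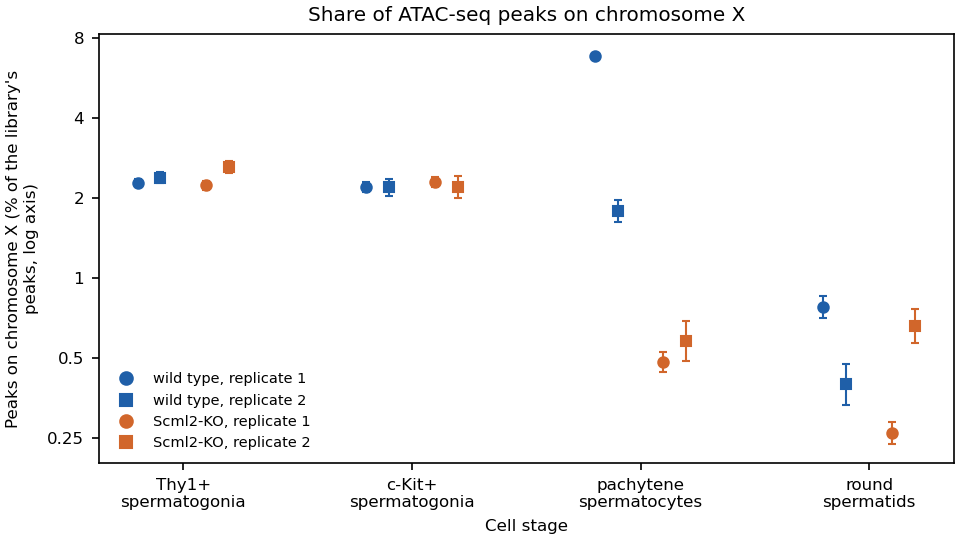
Share of each library's peaks on chromosome X (y axis, %, log scale) by stage (x axis), with Wilson 95% intervals. PS wild type stands at 6.83% and 1.79%, PS Scml2-KO at 0.483% and 0.580%, and the 8 spermatogonial libraries between 2.19% and 2.62%. With lists of equal length, not drawn, PS wild type stood at 2.85% and 1.60%.

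**Figure D4:**
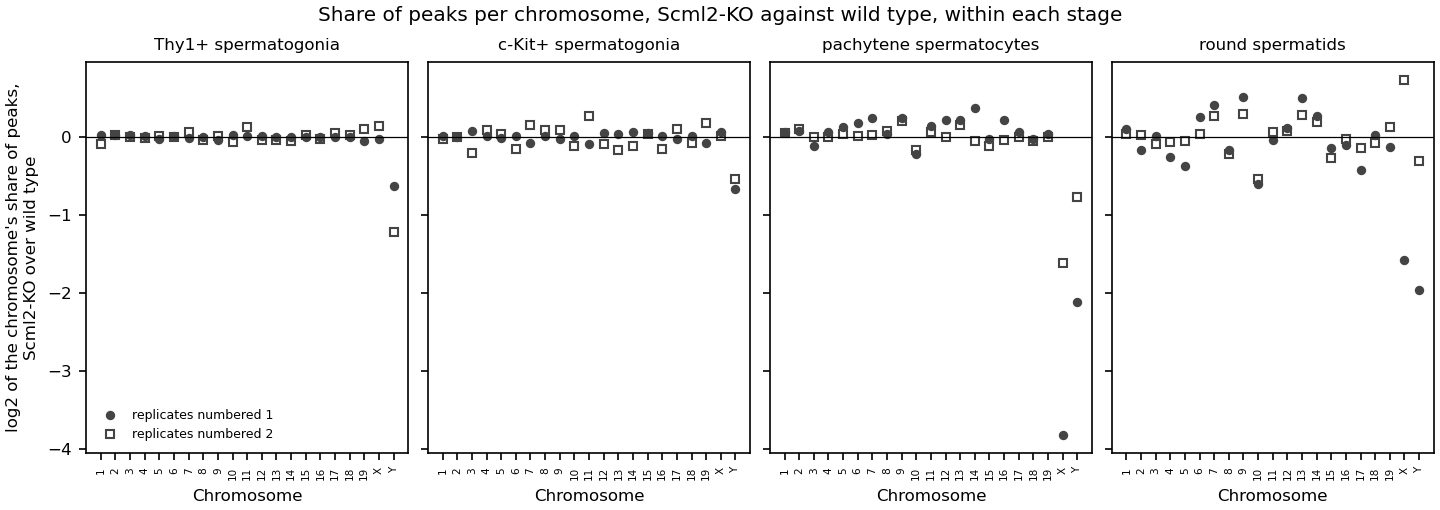
Log2 ratio of Scml2-KO to wild type (y axis) for the share of peaks on each chromosome (x axis) in each stage. Points are ratios of libraries with the same replicate number, shown filled for number 1 and open for number 2. X averages −2.72 in PS. In the ratio of means it stands at −3.02 there, while the autosomes lie between −0.20 and 0.22.

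Chromosome Y carried few peaks, 11 to 234 per library. Its share was 0.0399% ± 0.0252 in Scml2-KO and 0.0888% ± 0.0824 in wild type (SD, n = 8 each, exact p = 0.0154, adjusted p = 0.129), and the group mean was lower in Scml2-KO in 4 of 4 stages. PS stood above RS, 0.137% ± 0.0962 against 0.0397% ± 0.0189 (SD, n = 4 each, exact p = 0.0286, the smallest possible, adjusted p = 0.129, or exact p = 0.0556 within replicate numbers). Spermatogonia and adult cells had 0.0403% ± 0.0252 and 0.0884% ± 0.0826 (SD, n = 8 each, exact p = 0.107, adjusted p = 0.320).

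Near a TSS lay 30.2% ± 16.2 of peaks in spermatogonia and 33.4% ± 16.6 in adult cells (SD, n = 8 each, exact p = 0.697, adjusted p = 0.8). Scml2-KO and wild type had 33.1% ± 19.8 and 30.5% ± 12.2 (SD, n = 8 each, exact p = 0.755, adjusted p = 0.8), and PS and RS 34.7% ± 20.3 and 32.2% ± 15.1 (SD, n = 4 each, exact p = 0.8, adjusted p = 0.8). The share followed list length, with 19.3% ± 5.42 in the 8 longer lists numbered replicate 1 and 44.3% ± 12.5 in the 8 numbered replicate 2. At equal list length the difference between spermatogonia and adult cells turned to 2.89 points (exact p = 0.210). The difference between Scml2-KO and wild type turned to −2.77 without cKit Scml2-KO replicate 2, −1.14 without PS wild type replicate 1, −2.39 without PS Scml2-KO replicate 2 and −1.77 without RS Scml2-KO replicate 2.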

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

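The tests of list length, weak peaks and carry-over in this part were chosen only after the results were seen. Counts over the splits of a step and over the mixed splits within a stage were planned, and the other splits were not. The rule used to judge the splits was written after the results were seen. The difference of genotype effects between stages was not among the tests fixed beforehand.

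For the X chromosome share of peaks, the log2 ratio of Scml2-KO to wild type in PS differed by −2.61 from that of the other stages (exact p = 0.0357, adjusted p = 0.143). Both are the smallest values that 28 arrangements and 4 stages allow, so failing adjustment was fixed by the design. The ratio was −3.82 and −1.62 for replicates 1 and 2 of PS, and −1.57 and 0.73 for those of RS. For X-linked genes with a promoter peak the difference was −1.65 (exact p = 0.0357, adjusted p = 0.143), and with the same number of peaks in every library −2.55 for the X share (exact p = 0.0357, adjusted p = 0.143). With numbers crossed between the genotypes, the exact p for X-linked genes was 0.143.

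Fewer X peaks in PS Scml2-KO than in PS wild type could come from list length, from weak peaks near the calling threshold or from spermatogonia carried into the wild-type fraction. List length is argued against, since the lower wild-type X share was 4.13 times the higher Scml2-KO share with lists of equal length, and so are weak peaks, at 4.19 times with a fold enrichment of 5 or more. Carry-over predicts more spermatogonial peaks on autosomes in wild type, yet of 1571 autosomal regions open in all 8 spermatogonial and 0 RS libraries, PS wild type held 11.6% and 4.14% and PS Scml2-KO 12.4% and 7.26%, a difference of −1.97 points. At 89 such regions on X the values were 69.7% and 14.6% against 8.99% and 7.87%. The genotype stays open as a biological hypothesis, with 2 libraries on each side and a test between stages that could not pass adjustment. So does the mix of spermatocyte substages, which was not tested.

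RS Scml2-KO had 2817 regions open in both its libraries alone, against 1201 in wild type alone, a ratio of 2.35. List length may account for this order, since with lists of equal length the ratio was 0.547 (801 against 1464). Carry-over of spermatogonia cannot be told apart, because the 2 Scml2-KO libraries disagree. Of 1835 autosomal regions open in all 8 spermatogonial and 0 PS libraries, they held 0.109% and 5.01%, against 0.490% and 0.981% in wild type, a difference of 1.83 points. A genotype effect on RS stays open as untested.

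Somatic marker promoters were open in more spermatogonial than adult libraries, which may reflect list length and weak peaks, carried-over somatic cells or the chromatin of young germ cells. With lists of equal length the Sertoli and peritubular lists still differed, by 36.9 and 41.7 points (exact adjusted p = 0.000435 each), which argues against list length, whereas the endothelial and immune lists differed by 8.33 and 3.41 points (exact adjusted p = 0.166 and 0.233). They did pass with a fold enrichment of 5 or more (29.2 and 13.6 points, exact adjusted p = 0.0207 and 0.0359) and minus the share of all genes (26.3 and 12.2 points, 0.00272 and 0.00174), so list length may or may not account for these 2 lists. Somatic cells cannot be told apart from germ cells for the Sertoli list, whose promoter peaks had a median fold enrichment 0.645 times that of housekeeping promoters (0.598 to 0.825 over 8 libraries), since no pure fraction sets the ratio to expect. The ratio was 0.555 for peritubular, 0.384 for endothelial and 0.429 for immune markers. Of the genes, 2 of 21 Sertoli, 0 of 12 peritubular, 2 of 12 endothelial and 4 of 11 immune had a peak in no spermatogonial library. How far Thy1 or c-Kit selection removed somatic cells was not measured. Age differs with class and stays open as untested.

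A signal outside the main measurement was 576 summits on the mitochondrial chromosome, 28 to 51 in each of the 16 libraries, with RS Scml2-KO replicate 1 the highest.

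Other splits of the libraries were set against each count. Spermatogonia against adult cells gave 1300 genes and 29640 regions against at most 0 in the others. Of 100 drawn splits 1 was as large, the real one. Among the 35 splits that keep same-numbered libraries of a stage together, the real one was again the largest (1 of 35), with at most 140 genes and 6921 regions in the others. Neither kind of split was held to keep same-numbered libraries of Thy1 and cKit, or of PS and RS, together. Those libraries were taken as paired above, so these splits do not exclude chance. For cKit against PS the real split was the largest, with 503 genes against at most 196 and 4567 regions against at most 2098 (1 of 35 each). These splits take same-numbered libraries of a stage as independent, although they were taken as paired above. The 18 splits within numbers, with at most 30 genes and 131 regions in the others, are too few for a share under 0.05. Chance is therefore not excluded for this step. Nor can chance be excluded for Thy1 against cKit, with 51 genes against 130 (4 of 35) and 1912 regions against 4964 (3 of 35). The same holds for PS against RS, with 68 against 215 (3 of 35) and 594 against 3754 (5 of 35). Only 8 splits part the same pairs of libraries in these 2 steps, too few for a share under 0.05, and the highest others were 4 genes and 120 regions for Thy1 against cKit and 8 and 50 for PS against RS. In each step the highest other split set replicate 1 against replicate 2, and where it gave several times the real count it points to a structure of the samples, since the lists numbered 1 were longer. For genotype at an unadjusted p under 0.05, drawn splits gave up to 441 genes against 14 (31 of 100 as large) and 6005 regions against 100 (37 of 100), and these far larger counts again point to a structure of the samples, since such splits can put the longer lists on 1 side. Among the 128 splits that part each pair of same-numbered libraries of a stage, the highest others were 17 genes (6 of 128 as large) and 89 regions (1 of 128). Among such splits alone the real count of regions was the largest, 100 against 89, while for the genes another split gave more than the real one. Because these splits rest on a pairing inferred from the same data, they do not exclude chance for a genotype effect. After adjustment 0 genes and 0 regions passed.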

How the results depend on the processing

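The log2 X and Y shares and the adjusted test of the steps were chosen after seeing the data, and all other alternatives were planned. List length, which followed replicate number, limits these results. Of the values for named genes of the class comparison, 1057 kept their side of the threshold, 90 lost the call and 28 gained it. For single lists by class, 294 values kept it, 28 lost it, 21 gained it and 7 turned. Genotype called 0 genes, regions and lists in every alternative run, although 42 of 322 list differences changed sign in 12 lists (lowest exact adjusted p = 0.721). The X share by genotype and PS against RS stayed on its side in all, the Y share did so in 18 of 22 and 7 of 16. Where no construction is named, the cause was not tested. Motif tests were not run.

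The counts were 1300 genes and 29640 regions for class, 51 and 1912 for Thy1 against cKit, 503 and 4567 for cKit against PS, 68 and 594 for PS against RS. At −log10 q of 5 or more they were 15504 class regions, 678 Thy1-cKit and 2522 cKit-PS regions, and 105 PS-RS genes. Within stages this gave 145 Thy1 Scml2-KO, 294 cKit wild type, 31 cKit Scml2-KO, 646 PS wild type, 343 PS Scml2-KO, 483 RS wild type and 1519 RS Scml2-KO regions. The X share by class was then 1.37 points (exact p = 0.00513). The DNA damage response list turned to −1.5, and Cox7a1 and Lemd1 to −1.

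With fold enrichment of 5 or more they were 17313 class and 512 Thy1-cKit regions, 143 PS-RS genes, and within stages 2388 Thy1 wild type, 225 Thy1 Scml2-KO, 29 cKit Scml2-KO, 554 RS wild type and 1437 RS Scml2-KO regions, with an X share by class of 1.28 (exact p = 0.00622).

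The same number of peaks in every library gave 2129 class genes, 8010 class regions, 406 Thy1-cKit regions, 1109 cKit-PS genes, 324 PS-RS genes and 1363 PS-RS regions. Within stages it gave 533 Thy1 wild type, 440 Thy1 Scml2-KO, 292 cKit Scml2-KO and 801 RS Scml2-KO regions. Replicate agreement went from 0.310 to 0.598, the X share by class to 1.45 (exact p = 0.00155) and the promoter share by class from −3.22 to 2.89. The DNA damage response list turned to −7, the stem and progenitor list to −2.27 and Tmem151b to −1.

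Testing all features gave 624 class genes and 1868 regions, by a wider adjustment. Fisher's exact test with adjustment called 0 genes and 0 regions in each step. In either genotype alone, completely separated class features pass adjustment together or not at all. Wild type alone, 4 libraries against 4, gave 11748 class regions. For the steps it gave 440 and 15416 for Thy1-cKit, 1615 and 18977 for cKit-PS, and 631 and 4740 for PS-RS, more by construction since 2 libraries face 2. Its X share by class was −0.19 (exact p = 1), its Polycomb list 1.61, and 0 lists passed. Scml2-KO alone gave 0 class genes and 0 regions, 190 and 5578, 923 and 7503, and 435 and 3976 for the steps, with an X share of 1.84 (exact p = 0.0286), a promoter share of 1.27 and 0 lists. Minus the share of all genes, the DNA damage response list was −4.01 and the housekeeping list −3.41, and the Polycomb (−7.22) and pachytene (−19.95) lists passed. A TSS window of 500 bp put Lemd1 at −1. The log2 X share differed by 1.504 (exact p = 0.00855).

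Leaving out each library gave 1325 to 2409 class genes (highest without cKit Scml2-KO replicate 2), 19220 (without PS wild type replicate 1) to 42889 regions, 52 to 148 and 2002 to 7566 for Thy1-cKit, 541 to 884 and 4730 to 12676 for cKit-PS, and 91 to 199 and 757 to 1423 for PS-RS. The promoter share by class ranged from −8.00 to −0.0942 and by genotype from −2.77 (without cKit Scml2-KO replicate 2) to 7.94, the X share by class from 0.654 to 1.59 (without PS wild type replicate 1). The Polycomb list ranged from −2.19 to 1.04 (without cKit Scml2-KO replicate 2).

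Whether numbers pair the libraries was settled after both fits had been seen. A replicate block took the Y share of PS against RS to an exact p of 0.0556 and changed no other call between genotypes or in that step, with 0 genotype genes, 0 regions and 0 lists. At an unadjusted exact p under 0.05 the block left 1 gene higher in Scml2-KO and 1 in wild type, and 1 and 20 regions. For class, where the libraries share only a number, it gave 2232 genes and 37582 regions, and of 16 libraries 10 lay closest to the other genotype's library of their stage and number. For the step counts, labels permuted within numbers allow no exact p under 0.0556, so a blocked test can call 0 features.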

Other observations

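The gene families and the part of X in this section were chosen after the data were seen.

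Zinc finger genes named Zfp stood out among symbol families between spermatogonia and adult cells. Of 52 tested Zfp genes, 26 were higher in spermatogonia, such as Zfp108, Zfp111 and Zfp114, against 24.7% of all tested genes (Fisher's exact test, adjusted p = 0.00503 over 72 tests of 36 families with at least 8 tested members). Genes of the Il family, interleukins and their receptors, had 11 of 19 higher in spermatogonia (exact adjusted p = 0.0360), and cytochrome P450 genes named Cyp 8 of 12 (adjusted p = 0.0360). Higher in adult cells were 8.50% of all tested genes, against 27 of 176 genes named Gm, a larger share, and 0 of 80 microRNA genes named Mir, a smaller share (exact adjusted p = 0.0360 each). Collagen genes with 12 of 25 higher in spermatogonia and Prss serine protease genes with 4 of 11 higher in adult cells did not pass (exact adjusted p = 0.0940 each). Neighboring family members can share a region, so their calls are not independent.

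The peaks left on X in PS Scml2-KO lay to a large part at the distal end. This stretch also holds the Scml2 gene, and peaks of the pseudoautosomal region within it were not counted apart. Beyond 160000000 bp were 279 of 511 X peaks in replicate 1 (54.6%, 95% CI 50.3 to 58.9) and 41 of 127 in replicate 2 (32.3%, 24.8 to 40.8). PS wild type had 12.6% and 10.2% there, the 8 spermatogonial libraries 8.67% to 9.69%, RS wild type 9.54% and 20.2%, and RS Scml2-KO 10.5% and 12.3%. Outside the distal end, PS Scml2-KO had 232 and 86 X peaks, against 5093 and 398 in PS wild type.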
